A study of Mus musculus with 12 samples.

How the data were processed

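Tumours were flash frozen, and 1 ug of total RNA per sample was made into TruSeq libraries for 12 samples, per the labels. The labels give 4 groups of 3 samples: floxed Miz1, hepatocyte knockout of Miz1, floxed Miz1(POZ) and hepatocyte knockout of Miz1(POZ). They do not say how many mice the tumours came from. Bcl2fastq 2.19.0, Trimmomatic 0.36, Bowtie2 2.2.6, RSEM 1.1.17, edgeR 3.18.1, DESeq2 1.16.1 and the mm10 genome are listed per the submitters' processing notes, without a role or order. Which tool made which table is not given in the sources used here.

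The deposited Miz1 table holds a signal per gene that is read counts divided by 1 factor per library. In 5 of the 6 columns 100% of values above 0 were whole multiples of the value of 1 read (tolerance 0.01 reads). For floxed replicate 3 the value of 1 read fell within the tolerance that the check allows around a power of 10, so no reads are claimed for it. That was a limit of the check and not rounding of the values. Low values there, such as 2.01989 for Tbx21 and 3.02983 for Klrb1c, were not whole numbers. The recovered libraries hold 30151700 to 76123000 reads in genes and 50632400 to 135222000 in the whole column. In each column, 4 entries name no gene (unmapped, multimapping, no feature and ambiguous reads). They hold 38.0% to 50.8% of the column sums and were left out of tests. Of the 21751 remaining entries, 1426 are unannotated XLOC loci and 23 have symbols turned into dates. The locus XLOC_122887 had 0.961 to 1.05 times the value of Alb in each library.

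The deposited Miz1(POZ) table holds FPKM with 2 decimals for 24054 genes, of which 6636 are at 0 in all 6 libraries. RPKM cannot be told apart from FPKM by the values. Its depth is unknown, and no count test was run on it. Since neither table holds raw counts, the test fixed beforehand for normalised values was used in place of the one for counts.

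Within each table, genes with a mean value of at least 1 were tested with limma 3.58.1 (R 4.3.3, eBayes with trend) on log2(value + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that log2(value + 1) scale, which understates changes of low genes. Each SE of a log2 fold change is the moderated one of limma, which also draws on the spread of other genes. A set of 36 gene lists was fixed before the data were examined and tested with camera at a preset correlation of 0.01, where at least 4 members were measured, with an estimated correlation and fry beside it. A limma p adjusted over a list alone was adjusted within that list only, with no adjustment across lists. Mitochondrially encoded genes and pancreas, adipose or muscle genes were measured too little in both tables, and neutrophil, T and NK cell, and B and plasma cell genes too little in the Miz1(POZ) table. A single fit over both tables and a test of the difference between alleles had been planned and were not run, because the units differ.

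Genes were named by a rule also fixed then. It takes Zbtb17 and Mtdh, up to 8 genes past the threshold in each direction or, where none passed, the 5 of smallest unadjusted p, the 3 members of smallest p of each list that passed, and the 4 NF-kB targets of smallest p. Its part for the difference between alleles had no test to apply to, and 1 gene it names is not reported here. Most named genes were thus chosen for a small p, so a stable direction among them is no separate evidence. Coordinates are 1-based, from GENCODE M21 on GRCm38, which is mm10.

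Replicate numbers come from the sample titles. In the Miz1 table same-numbered libraries deviated together from their group means (correlations across genes of 0.489, 0.339 and 0.118), although knockout replicate 3 correlated more with floxed replicate 2 (0.282). As each same-numbered correlation was over 0.1, a fit paired by replicate number is given where it changes a call. The alternatives tried were another pseudocount, other filters, scalings and thresholds, robust moderation, the replicate block, and leaving out each library. Chosen after seeing the data were edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on the recovered reads of 5 libraries, leaving out XLOC loci, and leaving out both libraries of a replicate number.

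The tests were checked on simulated data with 200 changed genes. The simulated genes varied independently of each other, while real genes moved together (estimated correlation 0.615 within the Miz1 proliferation list). The rates of recovery and of false calls may therefore not hold for these libraries. At 4-fold changes limma recovered 53% of them among 21751 genes with the Miz1 spread and 98% among 11201 genes with the Miz1(POZ) spread; at 2-fold it recovered 0% and 67%. On 5 Miz1 libraries (19414 genes), edgeR recovered 0% at 4-fold and 83.5% at 16-fold, limma-voom 0% and 77%, and DESeq2 61% and 91.5%, with 90 and 124 unchanged genes called by DESeq2. Figures were drawn with matplotlib 3.10.9.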

Results

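RNA from liver tumours of C57BL/6 mice was sequenced in 12 libraries that fall into 4 groups of 3. Miz1, encoded by Zbtb17, is a zinc finger transcription factor whose POZ domain mediates protein interactions. Mice with a floxed Miz1 allele, or with a floxed allele of its POZ domain, were compared with mice of the same floxed genotype that carried Cre recombinase under the albumin promoter, a hepatocyte-specific knockout. Tumours had been induced with diethylnitrosamine (25 mg/kg at 2 weeks of age) and weekly carbon tetrachloride (0.5 ml/kg), and were taken at 5 months. The Miz1 tumours were given as read counts divided by a size factor per library. Reads in genes numbered 37115100 and 32278300 in floxed replicates 1 and 2, and 31370200, 30151700 and 76123000 in knockout replicates 1, 2 and 3; they are not claimed for floxed replicate 3. The Miz1(POZ) tumours were given as FPKM, and their depth is unknown. Because the tables hold different units and were normalised separately, each knockout was tested only against its own floxed control.

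The first comparison asked what differed in tumours when Miz1 was deleted in hepatocytes, with NF-kB target genes and metadherin of particular interest because the series title names both. Interferon response genes were higher in knockout tumours for 26 of 27 (median log2 fold change 0.38) and NF-kB target genes for 26 of 31 (0.28). Macrophage, matrix and proliferation genes were higher too, and cytochrome P450 genes were lower for 22 of 24 (-0.42). These lists passed at a preset correlation and not with an estimated one (adjusted p = 0.780 for each), and 0 single genes passed. Each of these list calls was also lost without floxed replicate 2, and each except interferon without knockout replicate 1. NF-kB, macrophage, matrix and proliferation genes each turned direction in 1 of the 6 fits that left out 1 library. Zbtb17, on chromosome 4 from 141444654 to 141467930 in GRCm38 (GENCODE M21), was at 323, 306 and 302 normalised reads in the floxed libraries and at 261, 271 and 267 in the knockout libraries. The 3 knockout values lay below the 3 floxed values, with a log2 fold change of -0.22 ± 0.14 (moderated SE). That SE draws on other genes. The SD of Zbtb17 itself was 10.9 normalised reads in floxed and 5.07 in knockout libraries (n = 3). The labels do not say which exons were removed, so a value summed over the gene checks the genotype only in part. Mtdh, which encodes metadherin, was at 3002 ± 243 in floxed and 3344 ± 200 in knockout tumours (SD, n = 3; log2 fold change 0.16 ± 0.13 SE). The libraries of the groups overlapped. The value was higher in the knockout library of 3 of 3 same-numbered pairs, but the labels do not say that the numbers pair the samples.

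Of 21751 genes and loci tested with limma, 0 passed an adjusted p of 0.05 (smallest 0.9998). At an unadjusted p under 0.05 there were 364, of which 171 were higher and 193 lower in the knockout, against 1088 given by chance. Groups did not overlap for 5.62% of genes, and chance gives 10%. With samples paired by replicate number, 0 genes passed (smallest adjusted p = 0.908) and 1150 had an unadjusted p under 0.05, so the shortfall against the 1088 of chance held only for the unpaired fit. On the reads of 5 libraries, edgeR and limma-voom called 0 genes (195 and 159 at an unadjusted p under 0.05) and DESeq2 called 5 (321 at an unadjusted p under 0.05). In data simulated for those 5 libraries with independent genes, DESeq2 called 90 unchanged genes beside 61% of 200 genes changed 4-fold.

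The 5 genes or loci of smallest p in the Miz1 comparison, none of which passed, were XLOC_041715, Per1, XLOC_089650, Ddit4 and Setd4. Per1, a repressor of the circadian clock (chromosome 11, 69095217 to 69109960), was at 2408 ± 248 normalised reads in floxed and 986 ± 253 in knockout tumours (SD, n = 3; log2 fold change -1.32 ± 0.22 SE). Ddit4, an inhibitor of mTORC1 signalling (chromosome 10, 59949669 to 59951834), was at 911 ± 294 and 333 ± 45.5 (log2 fold change -1.41 ± 0.26 SE). Setd4, a SET domain methyltransferase gene (chromosome 16, 93583457 to 93604063), was at 482 ± 60.1 and 256 ± 31.5 (log2 fold change -0.91 ± 0.17 SE). The unannotated loci XLOC_041715 and XLOC_089650 had log2 fold changes of -1.42 ± 0.22 and 1.69 ± 0.28 (SE). The limma adjusted p of each was 0.9998.

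**Figure D1:**
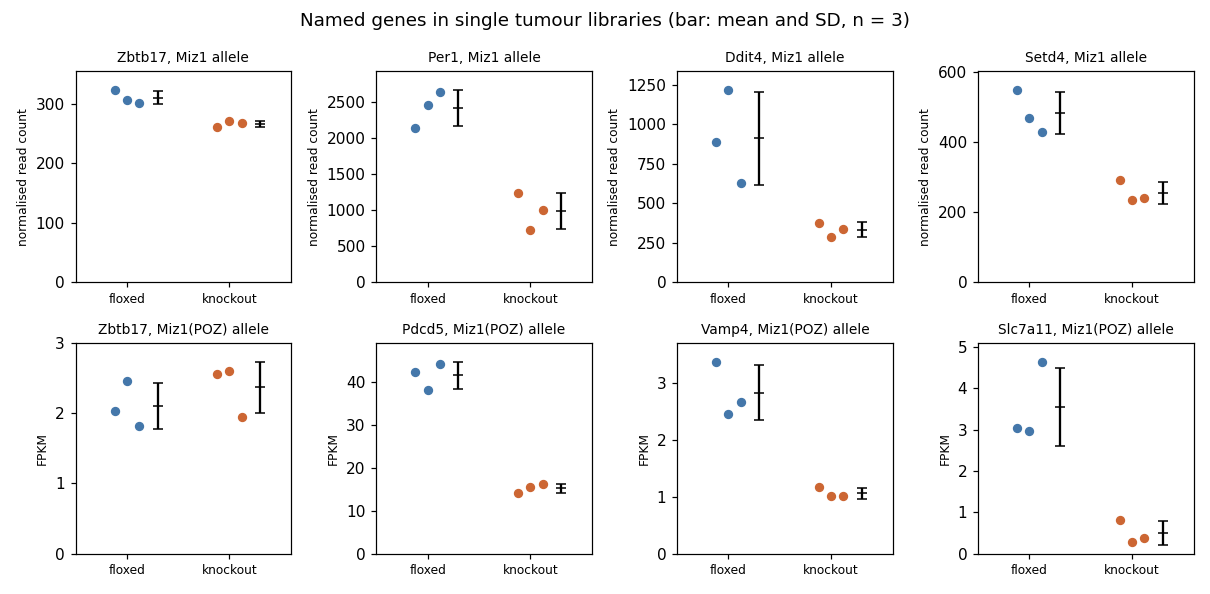
Expression of 8 panels of named genes in single tumour libraries (points), with the mean and SD of each group of 3 (black bars); the vertical axes start at 0 and give normalised reads for the Miz1 allele and FPKM for the Miz1(POZ) allele. In each panel except Zbtb17 of the Miz1(POZ) allele, the 3 knockout libraries lie below the 3 floxed libraries.

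Interferon response, macrophage, extracellular matrix and proliferation genes stood higher, and cytochrome P450 and other xenobiotic genes lower, in Miz1 knockout tumours when fixed gene lists were ranked against all other genes. Of 34 lists tested with camera at a preset correlation, 14 passed, 10 higher and 4 lower. With an estimated correlation within lists, 0 passed (adjusted p = 0.780 for each of the 14), and fry called 0 (smallest adjusted p = 0.925). A later count took the 10 splits of the 6 libraries into 3 and 3, the real one included. As small a camera p came from 6 of them for NF-kB targets and from 3 for interferon genes. No list had a member past the gene test, over all genes or adjusted over the list alone, so the values that follow describe lists and not changed genes.

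Of 27 interferon response genes, 26 were higher in Miz1 knockout tumours (median log2 fold change 0.38, camera adjusted p = 0.000321). Gbp6, an interferon-induced GTPase, was at 252 ± 52.0 in floxed and 401 ± 43.3 in knockout tumours (SD, n = 3), and Rsad2 and Cxcl9 had log2 fold changes of 0.56 and 1.11. Of 31 NF-kB target genes, 26 were higher (median 0.28, adjusted p = 0.0112), including Bcl3 (0.34 ± 0.16 SE), Tnfaip2 (0.79 ± 0.39), the chemokine gene Cxcl2 (1.12 ± 0.65) and the adhesion molecule Icam1 (0.53 ± 0.33). Acute phase genes were higher for 19 of 23 (adjusted p = 0.0295), among them Apcs (4197 and 6762 normalised reads on average), Il1rn (log2 fold change 1.41) and Hamp (0.78). Among proliferation genes 28 of 32 were higher (median 0.42, adjusted p = 0.00861). Aurka, a mitotic kinase, was at 110 ± 15.5 and 170 ± 4.95, while Cenpf (1.29 ± 1.04 SE) and Ccnb1 (1.36 ± 1.18 SE) varied more within groups. Markers of hepatocellular carcinoma were higher for 19 of 21 (median 0.71, adjusted p = 0.0136), with Igf2bp3 at 0.81, Anxa5 at 0.71 and Cd34 at 0.58.

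Macrophage and monocyte markers were higher in Miz1 knockout tumours for 22 of 25 (adjusted p = 0.0112; Cybb 1.29, Fcgr1 0.94, Cd14 1.24), and genes of pro-inflammatory macrophages for 11 of 11 (adjusted p = 0.0198; Nos2 0.69, Il1b 0.74). Extracellular matrix and stellate cell genes were higher for 26 of 27 (adjusted p = 0.00219; Postn 0.54, Acta2 0.93, Lox 0.72). T and NK cell genes were higher for 16 of 22 (adjusted p = 0.0112), where Klrb1c and Tbx21 were higher (1.21 and 0.99) and Foxp3, the regulatory T cell factor, was lower (-0.44). Hepatocyte genes were lower for 17 of 25 (adjusted p = 0.0338; Arg1 -0.45, Tat -0.82, Cps1 -0.56). Cytochrome P450 and other xenobiotic genes were lower for 22 of 24 (median -0.42, adjusted p = 0.000582), including Cyp2b10 (-2.50 ± 1.23 SE), its nuclear receptor Nr1i3 (-0.91 ± 0.49) and Por (-0.81 ± 0.47). Oxidative phosphorylation genes were lower for 20 of 22 (median -0.13, adjusted p = 0.00861; Cyc1 -0.28, Uqcrc1 -0.24, Cox5a -0.33). NRF2 target genes were lower for 15 of 20 (adjusted p = 0.04997; Ephx1 -0.33, Gsta2 -0.58, Ugdh -0.33). Genes with female-biased liver expression were higher for 12 of 14 (adjusted p = 0.0330; Cyp2c69 2.28), although Cyp17a1 was lower (-1.83, and -0.40 without knockout replicate 1). The Y-linked gene Ddx3y was at 3479 to 4154 normalised reads across the Miz1 libraries and at 20.8 to 25.4 FPKM across the Miz1(POZ) libraries. Male tissue was thus present in every library.

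Of the 14 Miz1 lists, 2 kept their call and direction without floxed replicate 2 and 3 did so without knockout replicate 1. Without floxed replicate 1 the number was 11, and it was 12 without floxed replicate 3, knockout replicate 2 or knockout replicate 3. NF-kB target genes lost their call without floxed replicate 2 (adjusted p = 0.171) and without knockout replicate 1, where the direction turned (0.568). The fold of 13 genes named here moved by over 1.5 times without 1 library: 10 without floxed replicate 1, 10 without floxed replicate 2, and 6, 4 and 2 without knockout replicates 1, 2 and 3. Il1rn went from 1.41 to 0.09, Cxcl9 from 1.11 to 0.38 and Tat from -0.82 to -0.23 without floxed replicate 2, Hamp from 0.78 to 0.14 without floxed replicate 1, and Cybb from 1.29 to 0.47 without knockout replicate 1. The others were Apcs, Cxcl2, Cenpf, Ccnb1, Cd14, Cyp2b10, Cyp2c69 and Cyp17a1. The NRF2 call was lost with a stricter filter and under quantile and median-ratio scaling, the hepatocyte call under quantile scaling and the female-biased call under column-sum scaling. Paired by replicate number, 13 of the 14 kept their call, the female-biased list did not (adjusted p = 0.0525), and neutrophil (0.000569), bile acid metabolism (0.00175) and male-biased genes (0.00505) were added. The hepatic gene Cyp2e1 was at 6372 in floxed replicate 1 and 7059 in knockout replicate 1, against 57731 to 131465 in the other 4 libraries, a gene chosen after its values were seen. For the 20 lists without a call, the adjusted p ran from 0.0553 to 0.995. They were the lists for TNF and NF-kB pathway components, Miz1 targets, MYC targets, p53 targets, alternatively activated macrophages, neutrophils, B and plasma cells, endothelium, cholangiocytes and progenitors, bile acids, Wnt and pericentral genes, fatty acid and cholesterol synthesis, PPARalpha, the unfolded protein response, autophagy, male-biased genes, X and Y chromosome genes, immediate early genes and erythroid genes. The test's direction differed in sign from the median for p53 targets, endothelium, fatty acid synthesis and autophagy.

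**Figure D2:**
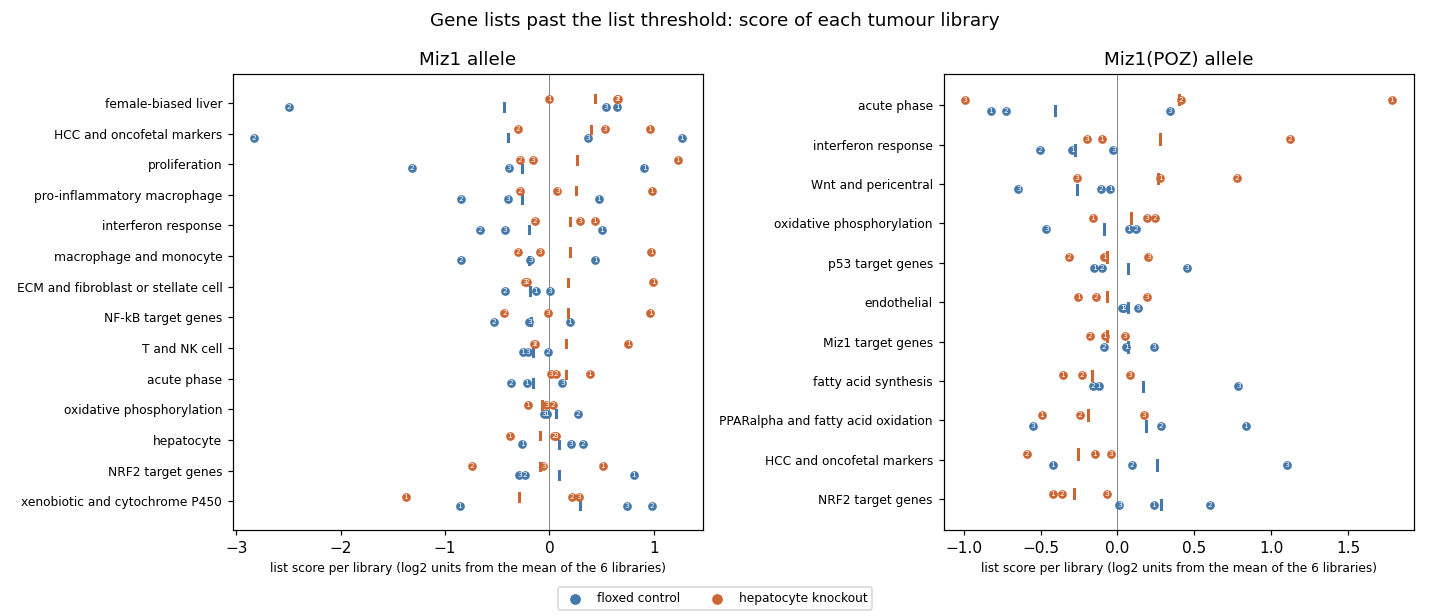
Score of each tumour library (horizontal axis, mean log2 difference of a list's genes from the average of the 6 libraries) for the lists past the list threshold; numbers in the points are replicates and vertical bars group means. The groups overlap for each list shown except NRF2 target genes of the Miz1(POZ) allele, where the 3 knockout libraries lie below the 3 floxed libraries.

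The second comparison asked the same of the POZ domain allele. NRF2 target genes, which encode antioxidant and detoxifying enzymes, were lower in Miz1(POZ) knockout tumours for 18 of 20 members (median log2 fold change -0.49, camera adjusted p = 1.68e-07). Adjusted over the list alone, 3 members passed, and 0 passed over all genes. Slc7a11, the cystine transporter (chromosome 3, 49892526 to 50443614), was at 3.55 ± 0.945 FPKM in floxed and 0.500 ± 0.282 in knockout tumours (SD, n = 3). The carbonyl reductase genes Cbr3 and Cbr1 were at 11.98 ± 2.90 and 179 ± 44.5 in floxed and at 2.89 ± 0.924 and 82.7 ± 15.8 in knockout tumours. The NRF2 call held without any single library, but not with an estimated correlation (adjusted p = 0.850). By fry, a move of the list's genes one way on balance did not pass (adjusted p = 0.521), and a change in either direction did (mixed adjusted p = 0.0427).

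Zbtb17 was at 2.03, 2.46 and 1.82 FPKM in floxed and 2.55, 2.60 and 1.95 in Miz1(POZ) knockout tumours (log2 fold change 0.12 ± 0.14 SE), so the groups overlapped. A deletion limited to the exons of the POZ domain need not lower the value of the whole gene, and the value therefore checks little. Mtdh was at 21.1 ± 2.03 and 24.2 ± 2.00 FPKM (SD, n = 3).

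Of 11201 genes tested with limma, 0 passed an adjusted p of 0.05 in the Miz1(POZ) comparison (smallest 0.0856). At an unadjusted p under 0.05 there were 976, of which 537 were higher and 439 lower, against 560 by chance, and the groups did not overlap for 15.0% of genes (10% by chance). The gene count became 1 without floxed replicate 1 (Rnu11), 2 without floxed replicate 2 (Eif3j1 and Mir3473g) and 4 without floxed replicate 3 (Gm13152, Mup16, Reep5 and Scara5), names given here after their values were seen. The 5 genes of smallest p, none past the threshold, were Pdcd5, Hist1h2bl, Per3, Miip and Gm13152, with limma adjusted p from 0.0856 to 0.0882. Pdcd5, linked to apoptosis (chromosome 7, 35641982 to 35647521), was at 41.5 ± 3.15 FPKM in floxed and 15.3 ± 1.06 in knockout tumours (SD, n = 3; log2 fold change -1.38 ± 0.12 SE). Miip (chromosome 4, 147860778 to 147868816) was at 5.42 ± 0.944 and 1.18 ± 0.333, and the clock gene Per3 (chromosome 4, 151003652 to 151044665) at 13.98 ± 1.29 and 4.31 ± 0.892. The histone gene Hist1h2bl was higher, at 1.47 ± 0.266 and 8.70 ± 2.29, and belongs to a family of closely similar genes. Gm13152 had a log2 fold change of -2.62 ± 0.29 (SE).

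Of 31 lists, 11 passed with camera in the Miz1(POZ) comparison, 4 higher and 7 lower, and 0 passed with an estimated correlation (adjusted p = 0.850 for each of the 11). Interferon response genes were higher for 26 of 27 (median 0.58, adjusted p = 9.95e-05). The list score was 1.13 in knockout replicate 2, while knockout replicates 1 and 3 (-0.10 and -0.20) lay within the floxed range of -0.50 to -0.03. The adjusted p was 0.0486 without knockout replicate 2, and the call was lost without both libraries of replicate 2 (0.604). Irgm1 was at 17.6 ± 1.03 FPKM in floxed and 33.7 ± 15.4 in knockout tumours (SD, n = 3), and Xaf1 and Rsad2 had log2 fold changes of 0.64 and 0.78 (0.35 for both without knockout replicate 2). Acute phase genes were higher for 20 of 23 (median 0.71, adjusted p = 0.0266; Orm3 2.11, and 1.34 without knockout replicate 1, Steap4 0.91), although Il1rn was lower (-0.63). The acute phase scores were -0.82, -0.73 and 0.34 in floxed and 1.79, 0.41 and -0.99 in knockout replicates 1, 2 and 3. Knockout replicate 3 was thus the lowest library, and the call was lost without floxed replicate 1, floxed replicate 2 or knockout replicate 1. Wnt and pericentral genes were higher for 11 of 14 (median 0.45, adjusted p = 0.0266). Of these, Slc1a2, a glutamate transporter, was at 5.03 ± 1.54 and 29.9 ± 12.3 FPKM. It passed when adjusted over the list alone (limma adjusted p = 0.00154) and not over all genes. Glutamine synthetase, Glul, was at 79.7 ± 9.49 and 156 ± 52.7. The Wnt call was lost without floxed replicate 3, knockout replicate 1 or knockout replicate 2. Oxidative phosphorylation genes were higher for 22 of 22 (median 0.15, adjusted p = 0.0363; Sdhb 0.47, Ndufa9 0.28, Ndufb8 0.31). These genes moved together (estimated correlation 0.915). Their list scores were 0.07, 0.12 and -0.46 in floxed and -0.16, 0.24 and 0.19 in knockout replicates 1, 2 and 3. The call was lost without floxed replicate 3, knockout replicate 2 or knockout replicate 3, and under quantile normalisation.

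PPARalpha and fatty acid oxidation genes were lower in Miz1(POZ) knockout tumours for 17 of 24 (median -0.32, adjusted p = 0.0134). On the list score, floxed replicate 3 was nevertheless the lowest library (-0.55). The call was lost without floxed replicate 1, knockout replicate 1 or knockout replicate 2. Vnn1, a pantetheinase, passed when adjusted over the list alone (limma adjusted p = 0.00781), and not over all genes (0.215). Fgf21 and Ppara had log2 fold changes of -1.82 (-2.53 without knockout replicate 3) and -0.49. Fatty acid synthesis and lipid droplet genes were lower for 16 of 20 (median -0.30, adjusted p = 0.0266; Cidec -1.56, Plin2 -0.88, Gpam -0.58). Their list scores were -0.12, -0.16 and 0.79 in floxed and -0.35, -0.23 and 0.08 in knockout replicates 1, 2 and 3. The call was lost without floxed replicate 3, knockout replicate 1 or knockout replicate 2. Carcinoma and oncofetal markers were lower for 11 of 17 (adjusted p = 0.0363; Myc -0.94, Gpc3 -1.73, Afp -1.81). Gpc3 was at 33.1, 84.1 and 313 FPKM and Afp at 15.3, 19.9 and 125 in the floxed libraries. Without floxed replicate 3 their log2 fold changes were -0.88 and -0.89, and the list lost its call there and without knockout replicate 2. The p53 target genes were lower for 12 of 17 (adjusted p = 0.0363; Plk2 -0.46, Aen -0.44, Mdm2 -0.28), and endothelial genes for 14 of 17 (adjusted p = 0.0363; Stab1 -0.34, Clec4g -0.31), although Vwf was higher (0.26). Among Miz1 target genes 6 of 12 were lower (adjusted p = 0.0363). Vamp4, a vesicle SNARE gene (chromosome 1, 162570515 to 162599084), was lower by log2 fold change (-0.89 ± 0.14 SE). It passed when adjusted over the list alone (limma adjusted p = 0.00414), and not over all genes (0.215). Exoc2 was at -0.35 and Vps28 at -0.42. By fry the Miz1 target list changed in either direction (mixed adjusted p = 0.00523). The Miz1 target, p53, carcinoma and endothelial calls were lost under each of 4 other scalings of the values. Of the 11 lists, 7 kept their call under median-ratio, TMM-like and column-sum scaling and 6 under quantile normalisation.

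NF-kB target genes were higher for 20 of 25 in Miz1(POZ) knockout tumours but the list did not pass (median 0.13, camera adjusted p = 0.153). Csf1 was at 2.38 ± 0.428 and 3.95 ± 1.03 FPKM (SD, n = 3), and Il1b, Rel and Nfkb2 had log2 fold changes of 0.80, 0.32 and 0.48. The NF-kB list did pass without a filter on low values (adjusted p = 0.0322), without floxed replicate 3 (0.0386) and without knockout replicate 3 (0.0315), and its direction turned with a mean of at least 5 (0.959), so the result depended on the filter and on single libraries. Of the 11 lists, 4 kept their call and direction without floxed replicate 3, 6 without knockout replicate 1 and 3 without knockout replicate 2, 9 without floxed replicate 1 or knockout replicate 3, and 10 without floxed replicate 2. The other lists without a call, 20 with NF-kB targets, had adjusted p from 0.0571 to 0.937. They covered TNF and NF-kB pathway components, proliferation, MYC targets, extracellular matrix, the 3 macrophage lists, cholangiocytes and progenitors, hepatocytes, xenobiotic metabolism, bile acids, cholesterol synthesis, the unfolded protein response, autophagy, male-biased and female-biased genes, X and Y chromosome genes, immediate early genes and erythroid genes. The filter of a mean of at least 1 FPKM left 12 of 32 proliferation genes, 7 of 16 pro-inflammatory and 5 of 16 alternatively activated macrophage genes. In the Miz1 table the filter kept all 21751 entries, so the lack of a call for these lists is no sign of a difference between the alleles. Within the proliferation list Ccnd1 (-1.48 ± 0.37 SE) and Ccne1 (-0.97 ± 0.22 SE), named after their values were seen, passed when adjusted over the list alone (limma adjusted p = 0.0329 for both). Neither passed over all genes. The median, mean and test differed in sign for proliferation, MYC targets, alternatively activated macrophages, the unfolded protein response and X and Y chromosome genes.

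Set side by side, the comparisons had 16 genes in the same direction at an unadjusted p under 0.05 and 0 past the threshold. Over 10842 genes tested in both, the log2 fold changes had a Pearson correlation of -0.02 and a Spearman correlation of 0.06 across genes, which are not independent replicates. Of the 16, 9 genes were higher in both (2.11 for independent lists) and 7 lower in both (2.88), while 3 and 6 went opposite ways (1.69 and 3.60). Setd4 was lower in both (-0.91 ± 0.17 and -0.96 ± 0.32 SE), and Vamp4, lower in Miz1(POZ), was at 0.21 ± 0.16 (SE) in Miz1 knockout tumours. Whether any gene changed differently between the alleles was not tested, since the tables differ in unit and normalisation.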

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

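The count tests on 5 libraries, the fit without XLOC loci and the fits without both libraries of a replicate number were chosen after the data were seen. The Miz1 gene count was 0 under each alternative run, except DESeq2 on the reads of 5 libraries, which called 5. These were Ighg2c, Ddit4, XLOC_089650, Igkv10-96 and XLOC_041715, named after their values were seen. In data simulated with independent genes, 200 of them changed, that test called 80 to 124 unchanged genes. Data without changed genes were not simulated, so the simulation does not show whether these 5 are false calls. Leaving out 1 library, or both libraries of a replicate number, gave 0 to 0 genes. The Miz1(POZ) gene count was 0 under each other alternative and 0 to 57 when libraries were left out, 57 of them without both libraries of replicate 3. The cause was not tested.

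The count of Miz1 lists was 14 in the reported fit and 0 with an estimated correlation and 0 with fry, and 6 to 19 when libraries were left out. The count of Miz1(POZ) lists was 11, and 0 with an estimated correlation and 0 with fry. It was 18 with no filter, of which 3 were lists with too few members otherwise, 6 with quantile normalisation, and 7 each with median-ratio, TMM-like and column-sum scaling, where 3 lists were lower and not 7. It was 4 to 15 when libraries were left out. The overlap of the comparisons was 0 genes, and 16 at an unadjusted p under 0.05. The NF-kB target list in Miz1(POZ) had an adjusted p from 0.00379 to 0.959 over its alternatives. The cause was not tested.

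With the replicate block, 0 genes passed in either comparison, 16 Miz1 lists passed, and 10 Miz1(POZ) lists, 9 of them among the 11 and the female-biased list beside them (adjusted p = 0.00957). In the Miz1(POZ) table the numbers were not shown to pair samples (correlations -0.09, 0.23 and 0.17), and not every library correlated best with its own number, which holds for the Miz1 table too. For the Miz1(POZ) clock genes, p by fry was 0.0520 with the block and 0.0490 without it. The planned fit over all 12 samples, the test of the difference between alleles, and count tests on the FPKM values were not run. In the 3 Miz1 knockout libraries the SD between libraries exceeded counting error for 84.7% of 21751 genes and loci, by a median of 2.55 times over all of them, and for the remaining genes the spread was no larger than counting error. For the FPKM values depth is unknown.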

Other observations

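The tests in this part were chosen after the results were seen, except the comparison of each count of genes past the threshold with other splits of the samples. Immunoglobulin variable segments, made by B and plasma cells, were higher in Miz1 knockout tumours for 78 of 80 (median log2 fold change 1.44), and 24 had an unadjusted p under 0.05. Their summed values were 555, 166 and 1694 in floxed and 2968, 880 and 1723 in knockout libraries, so the groups overlapped. The sum was higher in the knockout library of 3 of 3 same-numbered pairs, but the labels do not say that the numbers pair the samples. As a list the segments gave p = 0.0579 by camera with an estimated correlation.

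With Per1, Per2 and Per3 left out because they raised the question, clock genes of the phase of Dbp and Tef had lower values in Miz1 knockout tumours for 9 of 9 (median log2 fold change -0.43), and in Miz1(POZ) for 8 of 8 (-0.72). Camera with an estimated correlation gave p = 0.188 and 0.0737, fry gave p = 0.339 (0.0461 paired) and 0.0490, and genes of the opposite phase, such as Arntl, were higher for 5 of 5 and 4 of 4. On the difference of the phases, 3 of 3 same-numbered Miz1 pairs were lower (-0.85, -0.47 and -2.59), although the floxed Miz1 libraries spanned 3.79 (3.70 with the 3 genes kept) against a difference between groups of -1.30, while in Miz1(POZ) the groups did not overlap (difference -1.73, floxed span 0.59). Different collection times could give this: the smaller of the medians of the opposite phase was 0.376, above 0 as such a shift needs. An effect of the genotype could give the same values, and the explanations cannot be told apart because the labels give no times of day.

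The 14 genes lower in Miz1(POZ) knockout tumours at an unadjusted p under 0.001 and measured in both had a median of -1.42 in Miz1(POZ) and -0.09 in Miz1 knockout tumours, where 10 were lower and 0 had an unadjusted p under 0.05. They were chosen for a small p in Miz1(POZ), which tends to overstate their median there. Of 14 genes chosen in the same way but higher in Miz1(POZ), 5 were lower in Miz1 knockout tumours. None of these was higher there at an unadjusted p under 0.05. The spread between Miz1 libraries could hide a fall: the 95% interval excluded a change at 0.5 of the Miz1(POZ) size for 4 of the lower genes (Dynlt1b, Miip, Rasal2 and Vamp4), which leaves 10 open. The log2(value + 1) scale shrinks changes of low FPKM values (Vamp4 was at 2.83 FPKM in floxed tumours) more than those of larger values. The split into 4 and 10 depends in part on that scale. Little loss of Miz1 in the Miz1 tumours is also possible, as Zbtb17 was at 0.860 of its floxed level, but the deleted exons are not given. The lower genes include the clock genes Per2 and Per3, and Per3, Miip and Fblim1 lie within 10 Mb of Zbtb17. For these genes, different collection times or strain DNA near the locus, each raised in this part, stay open too. A difference between the alleles stays open and was not tested.

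In the Miz1(POZ) comparison, with Miip, Per3 and Gm13152 left out because they raised the question, 26 of 176 genes within 10 Mb of Zbtb17 (14.8%) had an unadjusted p under 0.05, against 8.56% of 10521 elsewhere (Fisher's exact test, two-sided p = 0.00646, across genes that are not independent). Of 83 windows of 20 Mb along the genome, 4 reached as high a share, and 1 of those overlaps the locus. In the Miz1 comparison the share near the locus was 9 of 287 (3.14%) against 1.52% elsewhere (Fisher's exact test, p = 0.0463), and 16 of 125 windows reached as high a share. Strain DNA near the locus that differs between the Miz1(POZ) groups could give the share of 14.8%, as a hypothesis, but the labels give both groups as floxed on both alleles, so DNA linked to the floxed allele is expected in both. An effect of the edited locus on its neighbours was not tested.

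For 3 samples against 3 there are 10 splits, too few for a share under 0.05. The Miz1 gene count of 0 was reached by 10 of 10 splits (highest other 1), and the Miz1(POZ) count of 0 by 10 of 10 (highest other 2). For Miz1 genes at an unadjusted p under 0.05, 8 splits reached the real 364 (highest other 3354). Splits with both libraries of replicate 1 on the same side gave 2706, 2829 and 3354, several times the real count, and 557, which points to a structure of the samples. The other 3 splits that part all 3 replicate pairs gave 215, 661 and 380. For Miz1(POZ), 2 splits reached 976 (highest other 1035). For lists, 6 splits reached the 14 of Miz1 (highest other 20) and 7 the 11 of Miz1(POZ) (highest other 21). The splits were also counted per list, the real one included. For Miz1, 6 of 10 gave as small a camera p for NF-kB targets, 7 for macrophage and 6 for carcinoma genes. The number was 5 for proliferation and matrix, 3 for interferon and P450, and 1 for hepatocyte genes. For Miz1(POZ) it was 9 for fatty acid synthesis, 7 for acute phase, and 6 for PPARalpha and oxidative phosphorylation. It was 5 for interferon and 1 for NRF2 genes.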
